A study of Homo sapiens with 28 samples.

How the data were processed

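Expression was measured in 28 libraries from 4 human liver tumour cell lines, HepG2, Hep3B, HuH7 and PLC/PRF/5, with 3 in vitro and 4 in ovo libraries per line. Per the labels' protocols, tumour cells were placed on the chorioallantoic membrane of white leghorn eggs at embryonic day 9 and tumours were removed at day 18, 9 days later. RNA came from cultures through a mini column kit and from tumours through a midi column kit, so the kit and the condition cannot be told apart. Per the labels' protocols, 500 ng of total RNA went into each library, made with DriverMap targeted amplicons. The genome build hg38 is named in the submitters' processing notes. The aligner, the counting and any filter are not given in the sources used here.

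The values deposited by the authors are a signal per amplicon that sums to 500000 in each library, not counts, although they are named as counts. Multiplying by 2 gave CPM, the usual scale with a fixed total per library. Low values rose in equal steps, from which the whole reads behind each value were recovered. At least 99.9565% of the values of each library lay within 0.01 of a whole read, and the largest departure was 0.113. Recovered depth was 6205368 to 8662998 reads in vitro and 6085750 to 15086465 in ovo, and a floor of 3 reads was taken per library. 1 damaged cell, that of KRT18 in PLC/PRF/5 in ovo replicate 2, was filled from the shortfall of its library's total (4021 CPM). 33 duplicated symbols were given distinct names. Gene symbols are those of the deposited table, in which CCN2 stands as CTGF and CCN1 as CYR61.

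Before the data were examined, the groups, the comparisons, edgeR's quasi-likelihood test, the lists of genes, the rule for named genes and a set of alternatives were fixed. Because the values turned out to be scaled and not counts, the test became limma with a trended variance on log2(CPM + 1), after TMM scaling, and edgeR's test on the recovered reads became an added alternative. The filter of edgeR (filterByExpr by group, at least 10 reads) kept 13100 of 18961 genes, and 5861 did not pass it. 1 fit to 8 groups, with 20 residual degrees of freedom, gave the difference in ovo minus in vitro in each line, its mean over lines and the line by condition interaction. P values were adjusted by Benjamini-Hochberg over genes within a contrast, and a gene was called at an adjusted p under 0.05. edgeR's count test called 1709 genes higher and 1443 lower in HepG2, 3345 and 2937 in Hep3B, 3243 and 1961 in HuH7, 1701 and 542 in PLC/PRF/5, and 4466 and 3374 in the mean of lines.

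33 lists of genes were fixed from general knowledge, of which 32 had enough measured members. They cover hepatocyte secreted proteins, hepatocyte transcription factors, drug metabolism, bile acids, the urea cycle and amino acid catabolism, gluconeogenesis, glycolysis, hypoxia, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, oxidative phosphorylation, mitosis, DNA replication, p53 targets, Wnt/beta-catenin targets, the unfolded protein response, ATF4 and the amino acid response, NRF2 targets, immediate early genes, the interferon response, class I antigen presentation, NF-kB and inflammatory mediators, the acute phase response, epithelial-mesenchymal transition, matrix remodelling, TGF-beta and YAP targets, oncofetal markers, and markers of endothelial cells, fibroblasts, leukocytes, stratified epithelium and erythroid cells. Each was tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the lists of a contrast. It was tested again with an estimated correlation and with fry. A difference of a list between 1 line and the mean of the other lines was tested with camera on that contrast. Several lists share regulators or members, so their tests are not independent.

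Named genes follow a rule. They are 24 key genes whatever their values, of which 22 were tested and 19 are reported here; per line the 8 highest and 8 lowest fold changes among called genes averaging at least 10 CPM whose 2 conditions do not overlap; the 10 highest and 10 lowest of the mean contrast among genes called alike in all 4 lines; the 10 smallest interaction p values among genes called in opposite directions; and up to 4 called members per list. Amplicon sequences were matched exactly to GENCODE 29 transcripts, which placed 18849 amplicons on GRCh38 and left 112 unplaced. 8572 lay within 1 exon and 10277 spanned 2 or more.

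The alternatives were DESeq2's size factors, total counts alone, no filter, a stricter filter (at least 10 CPM in 3 libraries), DESeq2's Wald test, limma-voom, each line fitted alone, the replicate number as a block, the 20 most abundant genes left out, a minimum of 2-fold, and each library left out in turn. Added after the data were seen were edgeR's test on recovered reads, pseudocounts of 0.25 and 5 CPM, removal of the trends with GC content and amplicon length, leaving out the 4 in ovo libraries numbered 3, and subtraction of the share of another line's in ovo profile from the PLC/PRF/5 and Hep3B in ovo libraries. The fit was tested on simulated data drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold of 13100, all taken from genes averaging at least 10 CPM in the line. It recovered 36% and 90% of them in HepG2, 44% and 88% in Hep3B, 42% and 92% in HuH7, and 45% and 90% in PLC/PRF/5, and called 14, 21, 28 and 27 of 12900 unchanged genes. The simulated libraries were independent, with 1 dispersion per gene for both conditions. These counts therefore do not give the error rate for real tumours, which spread more than cultures and can deviate together. R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0 were used. Genes without an amplicon, HBB among them, are not analysed here.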

Results

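Gene expression was measured in 4 human liver tumour cell lines, each grown in 2 settings. They were grown as cultures (in vitro) and as tumours on the chorioallantoic membrane of the chick embryo (in ovo), a well vascularised membrane on which grafted cells form solid nodules. HepG2 was derived from a hepatoblastoma, and Hep3B, HuH7 and PLC/PRF/5 from liver carcinomas. Each line gave 3 in vitro and 4 in ovo libraries, 28 in all. Cells were grafted at embryonic day 9 and tumours removed at day 18. The libraries were made with a targeted kit in which 18961 human amplicons are read, 1 per gene symbol apart from 33 duplicated symbols, and 13100 genes passed the expression filter. Depth was 6205368 to 8662998 reads in the 12 cultures and 6085750 to 15086465 in the 16 tumours. 3 reads thus corresponded to 0.199 to 0.493 CPM before TMM scaling, CPM being the share of a library's reads on the usual fixed total. On the scaled levels the floor is higher where the TMM factor is under 1, as in Hep3B tumours (0.447 to 0.711). Such floors cover counting error only, because amplified reads carry no molecular identifiers here. Levels are mean CPM after TMM scaling ± SD, with n = 3 in vitro and n = 4 in ovo. Fold changes are in ovo over in vitro on the log2(CPM + 1) scale, which understates the change of genes read at a few CPM. P values are limma's, adjusted by Benjamini-Hochberg. No label says whether replicates came from separate cultures or eggs, so p values measure the spread between these libraries, which may be technical. Amplicon positions are on GRCh38, and every position given lies in coding sequence.

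The question that the design poses is how the transcriptome of each line differs between the culture dish and the tumour in ovo. The lines kept their identity in both settings. Each of the 28 libraries was closest to another library of its own group. Line accounted for 72.1% of the sum of squares of log2 expression, condition for 9.38%, line by condition for 7.62%, and the spread within groups for 10.9%. The difference of each line from the mean of the other 3, taken across 13100 genes, correlated between in vitro and in ovo with Pearson's r of 0.889 in PLC/PRF/5, 0.812 in HepG2, 0.778 in HuH7 and 0.678 in Hep3B (Spearman's rho 0.851, 0.724, 0.739 and 0.6). Genes are not independent replicates, so these values describe the profiles. Replicate cultures correlated at 0.9911 to 0.9964 over 12 pairs and replicate tumours at 0.8711 to 0.9934 over 24 pairs, and no pair of libraries differed by as little as sampling noise. The fold changes in ovo over in vitro followed the GC content of the amplicons (Spearman's rho 0.274 in HepG2, 0.458 in Hep3B, 0.505 in HuH7 and 0.389 in PLC/PRF/5) and their length (-0.293, -0.485, -0.341 and -0.213).

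**Figure D1:**
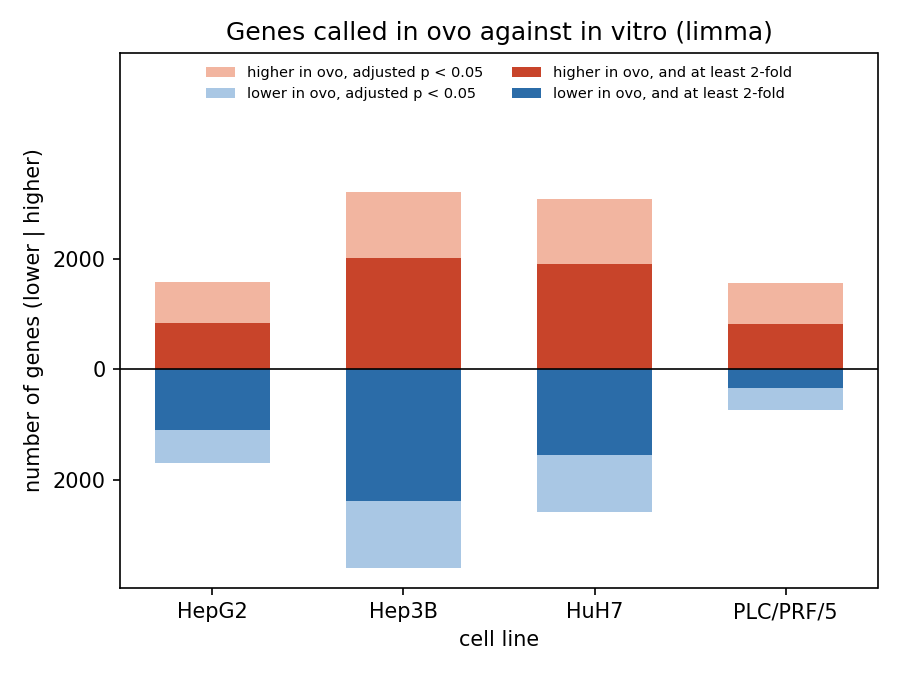
Number of genes called higher (bars above 0) and lower (bars below 0) in ovo than in vitro for each line, at a limma adjusted p under 0.05, with the part changed at least 2-fold in the darker shade. Hep3B had the most calls (3220 higher and 3594 lower) and PLC/PRF/5 the fewest (1557 and 735).

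In HepG2 tumours the lists of mitosis and DNA replication passed upward and those of immediate early genes and NRF2 targets downward. APOA1, the main protein of high density lipoprotein (chromosome 11, 116835841 to 116835934), rose from 3892 ± 462 to 34350 ± 14000 CPM (log2 fold change 3.07, adjusted p = 6.87e-07). The fetal serum protein AFP (chromosome 4, 73452483 to 73452599) rose from 7863 ± 118 to 23210 ± 3620 CPM (1.55, 3.7e-05). CYP7A1, the rate-limiting enzyme of bile acid synthesis (chromosome 8, 58492434 to 58494533), rose from 0.563 ± 0.246 to 24.6 ± 9.32 CPM (3.09e-13). EPO, the hormone of red cell production, rose from 12.2 ± 0.316 to 132 ± 18.6 CPM (5.08e-08). The largest rise among genes averaging at least 10 CPM was that of PGLYRP2, a peptidoglycan amidase secreted by the liver (chromosome 19, 15476308 to 15476422), from 0.649 ± 0.422 to 152 ± 61.1 CPM (6.47, 7.11e-14). The largest fall was that of the organic anion transporter ABCC3 (chromosome 17, 50676344 to 50676473), from 203 ± 11.3 to 2.7 ± 0.639 CPM (-5.80, 9.28e-17). The glucose transporter SLC2A1 fell from 8081 ± 476 to 344 ± 121 CPM (3.01e-09).

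Among the lists of genes fixed in advance, 12 passed camera in HepG2, 4 upward and 8 downward. Of the hepatocyte secreted proteins 10 of 23 measured members rose and 4 fell (10 and 4 adjusted over the list alone), list adjusted p = 0.00115. Plasminogen, PLG, rose by 3.38 and APOC3 by 2.41 on the log2 scale. Of the hepatocyte transcription factors 10 of 18 measured members rose and 1 fell (11 and 1 adjusted over the list alone), list adjusted p = 0.00426. ONECUT1 rose from 27.6 ± 2.62 to 349 ± 320 CPM. The adjusted p with an estimated correlation was 0.215 for each of these 2 lists. Of the mitosis list 15 of 25 measured members rose and 0 fell (15 and 0 adjusted over the list alone), adjusted p = 1.84e-06. Of the DNA replication list 12 of 25 measured members rose and 0 fell (12 and 0 adjusted over the list alone), adjusted p = 8.35e-06. Both also passed with an estimated correlation. TOP2A, the topoisomerase of dividing cells, rose from 250 ± 1.77 to 530 ± 42.6 CPM (3.62e-07), and the ribonucleotide reductase subunit RRM2 from 262 ± 24 to 1141 ± 679 CPM (0.000551). MCM2 of the replicative helicase rose from 268 ± 8.1 to 871 ± 465 CPM (0.00117) and the spindle protein TPX2 from 157 ± 2.53 to 414 ± 144 CPM (8.16e-06). MKI67 did not pass (log2 fold change 0.44, adjusted p = 0.671). In ovo replicate 3 had 13.8 CPM of it and the other tumours 88.6 to 111 CPM, against 43.7 to 46.6 CPM in the cultures.

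Of the immediate early genes, transcribed within minutes of growth factor stimulation, 1 of 20 measured members rose and 12 fell (1 and 14 adjusted over the list alone) (list adjusted p = 1.69e-08). FOSB (chromosome 19, 45472788 to 45472996) fell from 61.7 ± 4.66 to 0.275 ± 0.326 CPM (4.79e-15) and EGR1 from 633 ± 14.4 to 34.2 ± 9.01 CPM (8.76e-14). Of the NRF2 targets, enzymes against oxidative stress, 0 of 20 measured members rose and 12 fell (0 and 13 adjusted over the list alone) (list 9.32e-07). AKR1C2 fell from 463 ± 47.8 to 34.8 ± 17 CPM and the quinone reductase NQO1 from 420 ± 26.5 to 62.5 ± 25 CPM (4.44e-06). Both lists also passed with an estimated correlation. The list of ATF4 and the amino acid response had 13 of 21 members lower and 0 higher (0 and 13 adjusted over the list alone, list adjusted p = 1.72e-07 and adjusted p = 0.0802 with an estimated correlation). The pseudokinase TRIB3 changed by -2.67 and the folate enzyme MTHFD2 by -2.15. Matrix remodelling and adhesion had 14 of 24 lower and 0 higher (1 and 14 adjusted over the list alone, 1.7e-06, adjusted p = 0.0507 with an estimated correlation). The integrin ITGA2 fell from 192 ± 8.66 to 23.6 ± 3.49 CPM and osteopontin, SPP1, from 360 ± 56.1 to 48.4 ± 7.75 CPM. Of the TGF-beta and YAP targets 0 of 16 measured members rose and 9 fell (0 and 9 adjusted over the list alone). The list had an adjusted p of 5.27e-05 (adjusted p = 0.0642 with an estimated correlation). CTGF fell from 1051 ± 10.5 to 279 ± 125 CPM, and the receptor AXL changed by -3.57. Glycolysis had 8 of 20 lower and 0 higher (0 and 9 adjusted over the list alone, 0.000929, adjusted p = 0.245 with an estimated correlation). Fatty acid synthesis and lipid storage had 7 of 19 lower and 0 higher (0 and 7 adjusted over the list alone, 0.0101, adjusted p = 0.232 with an estimated correlation). The lipogenic regulator SREBF1 changed by -2.93. Of the epithelial-mesenchymal list 1 of 20 measured members rose and 6 fell (1 and 6 adjusted over the list alone). Its fallen members include the epithelial keratin KRT18 as well as fibronectin, FN1. It passed at 0.0353 (adjusted p = 0.215 with an estimated correlation). It no longer did with the 20 most abundant genes left out (0.102) or without HepG2 in ovo replicate 1 (0.103). Members of one list could part, as CYP7A1 rose and ABCC3 fell among the bile acid genes. That list's median was 0.27 and its mean -0.10 (adjusted p = 0.809).

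In total 1588 genes were higher and 1697 lower in HepG2 tumours, 844 and 1098 of them by at least 2-fold. Scaled to total counts alone, a choice that moved the median of all genes by -0.16 on the log2 scale, the split was 1199 higher and 2080 lower. In ovo libraries read 27.8% ± 18.9 of the 392 olfactory receptor amplicons, genes of the nasal epithelium, against 3.57% ± 0.51 in the cultures.

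Hep3B showed the largest number of calls, though without Hep3B in ovo replicate 3 it had 5725 against 6067 in HuH7. Its largest rises included the secreted proteins PGLYRP2 and SERPINC1, the protein disulfide isomerase AGR2 and AFP. AFP rose from 150 ± 6.45 to 15090 ± 2490 CPM (log2 fold change 6.63, adjusted p = 2.54e-16). PGLYRP2 rose from 1.38 ± 0.128 to 1068 ± 259 CPM (8.79, 8.1e-17), and antithrombin, SERPINC1 (chromosome 1, 173909696 to 173909823), from 1.14 ± 0.164 to 674 ± 178 CPM (8.27, 1.31e-18). AGR2 rose from 0.0894 ± 0.0775 to 127 ± 22.6 CPM (7.24e-17). CPS1, the entry enzyme of the urea cycle, rose from 6.1 ± 0.369 to 271 ± 110 CPM (5.77e-16), and arginase, ARG1, from 10.6 ± 0.783 to 184 ± 32 CPM (4.58e-09). Insulin-like growth factor 2, IGF2 (chromosome 11, 2133191 to 2133634), took 15.8% ± 4.04 of the reads in ovo against 6.63% ± 0.346 in vitro. After TMM scaling, which raises the levels of Hep3B tumours, IGF2 rose from 59380 ± 4710 to 281100 ± 79700 CPM (2.19, 0.00179). With total counts alone as the scale its call was lost (adjusted p = 0.0693), as it was with Hep3B fitted alone (0.442). The largest falls included CGA, the glycoprotein hormone alpha chain (chromosome 6, 87086320 to 87088122), from 240 ± 9.3 to 1.32 ± 0.541 CPM (-6.73, 1.75e-16). The signalling antagonist CER1 (chromosome 9, 14720120 to 14720263) fell from 139 ± 4.15 to 2.98 ± 2.05 CPM (1.46e-12), and neurotensin, NTS, from 14070 ± 311 to 432 ± 112 CPM (5.65e-11).

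Of the hepatocyte secreted proteins 16 of 23 measured members rose and 1 fell (17 and 1 adjusted over the list alone), list adjusted p = 2.75e-07 (adjusted p = 0.0577 with an estimated correlation). APOA1 rose from 758 ± 19 to 16670 ± 6770 CPM and transthyretin, TTR, from 82.2 ± 1.93 to 962 ± 145 CPM. Of the urea cycle and amino acid catabolism genes 12 of 17 measured members rose and 1 fell (12 and 1 adjusted over the list alone). The list passed at 2.15e-05 and also with an estimated correlation (0.0262). Of the drug metabolism genes 9 of 18 measured members rose and 1 fell (9 and 1 adjusted over the list alone) (list 0.00812, 0.0304 with an estimated correlation). CYP2D6 rose from 3.61 ± 0.72 to 64.6 ± 12.3 CPM. Of the gluconeogenesis genes 6 of 10 measured members rose and 0 fell (6 and 0 adjusted over the list alone) (list 0.00785, 0.0304 with an estimated correlation). The bisphosphatase FBP1 rose from 5.91 ± 0.683 to 34.6 ± 11.8 CPM. Of the bile acid genes 9 of 16 measured members rose and 0 fell (9 and 0 adjusted over the list alone) (list 0.0111, adjusted p = 0.0882 with an estimated correlation). The nuclear receptor NR0B2 rose from 411 ± 14.3 to 4724 ± 3230 CPM. Under the stricter filter on low counts these 3 lists no longer passed (0.107 for drug metabolism, 0.125 for gluconeogenesis and 0.166 for bile acids). Their median log2 fold changes were then 0.834, 0.892 and 0.403. Drug metabolism also missed with no filter (0.0793). Mitosis moved opposite to HepG2, and 1 of 25 measured members rose and 17 fell (1 and 17 adjusted over the list alone) (list 0.000248, 0.0304 with an estimated correlation). The kinase AURKB fell from 81.3 ± 1.32 to 11 ± 7.37 CPM and cyclin B1, CCNB1, from 49 ± 3.43 to 7.56 ± 5.88 CPM. Of the DNA replication genes 3 of 25 measured members rose and 12 fell (3 and 12 adjusted over the list alone). That list lay at 0.0492 (adjusted p = 0.2 with an estimated correlation) and missed without Hep3B in ovo replicate 1 (0.139) or in vitro replicate 2 (0.068). Of the inflammatory mediators 2 of 21 measured members rose and 12 fell (2 and 12 adjusted over the list alone) (list 0.00131, adjusted p = 0.0882 with an estimated correlation). The neutrophil chemokine CXCL8 fell from 32.5 ± 1.49 to 0.439 ± 0.124 CPM and CXCL5 from 112 ± 4.06 to 8.79 ± 5.14 CPM. Of the TGF-beta and YAP targets 1 of 16 measured members rose and 11 fell (1 and 11 adjusted over the list alone) (list 0.000474, adjusted p = 0.0882 with an estimated correlation). CTGF fell from 417 ± 3.28 to 31.1 ± 11.6 CPM and ANKRD1 from 41.2 ± 2.49 to 1.29 ± 1.22 CPM. Of the ATF4 list 2 of 21 measured members rose and 14 fell (2 and 15 adjusted over the list alone) (list 0.000727, adjusted p = 0.307 with an estimated correlation). The glutathione-degrading enzyme CHAC1 fell from 53.3 ± 2.29 to 6 ± 2.63 CPM.

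Hep3B had 3220 genes higher and 3594 lower in ovo, 2016 and 2380 by at least 2-fold. With total counts alone as the scale, which moved the median of all genes by -0.69 on the log2 scale, these became 1205 higher and 6820 lower. The balance between rises and falls moved with the scaling. Under the stricter filter 2332 genes were lower. The olfactory receptor amplicons were read at 19.8% ± 10.1 in ovo and 3.74% ± 0.15 in vitro.

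In HuH7 tumours the lists of cholesterol synthesis, fatty acid synthesis and NRF2 targets passed downward. Fatty acid synthase, FASN, fell from 13040 ± 379 to 2230 ± 1380 CPM (log2 fold change -2.72, adjusted p = 2.4e-06). AFP fell from 1878 ± 25.2 to 372 ± 141 CPM (-2.40, 4.58e-08) and the high density lipoprotein component APOA2 from 1437 ± 77.4 to 60.3 ± 21.1 CPM (2.84e-11). The largest fall was that of NQO1 (chromosome 16, 69713079 to 69718156), from 308 ± 4.37 to 9.37 ± 5.95 CPM (-5.07, 2.55e-10). The largest rises were those of the basement membrane protein nephronectin, NPNT (chromosome 4, 105967208 to 105967336), from 7.98 ± 0.338 to 835 ± 515 CPM (6.38, 6.25e-12), and the secretin receptor SCTR, from 0.777 ± 0.388 to 153 ± 66.4 CPM (3.29e-10). CER1 and LEFTY1, secreted antagonists of Nodal signalling, rose from 0.284 ± 0.0576 to 95.1 ± 32.5 CPM (2.24e-13) and from 3.13 ± 0.194 to 259 ± 85.7 CPM (4.99e-11).

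Of the cholesterol synthesis genes 0 of 23 measured members rose and 19 fell (0 and 19 adjusted over the list alone) (list adjusted p = 3.8e-12). HMGCS1 fell from 1552 ± 24.3 to 174 ± 92.9 CPM. Of the fatty acid synthesis genes 1 of 19 measured members rose and 15 fell (1 and 15 adjusted over the list alone) (list 1.25e-06). The desaturases FADS2 and SCD fell from 151 ± 6.22 to 9.3 ± 5.88 CPM and from 70.4 ± 2.78 to 3.89 ± 2.81 CPM. Of the NRF2 targets 0 of 20 measured members rose and 15 fell (0 and 15 adjusted over the list alone) (2.77e-08), and of the mitosis list 0 of 25 measured members rose and 13 fell (0 and 13 adjusted over the list alone) (0.000175). Of the DNA replication genes 0 of 25 measured members rose and 17 fell (0 and 18 adjusted over the list alone) (4.71e-06), and of the acute phase response 2 of 17 measured members rose and 12 fell (2 and 13 adjusted over the list alone) (0.000253). These 6 lists also passed with an estimated correlation. The acute phase plasma proteins ORM1 and ORM2, the products of a duplicated gene, fell from 1226 ± 8.25 to 104 ± 63.3 CPM and from 115 ± 2.83 to 6.04 ± 3.26 CPM. AURKB fell from 96.8 ± 4.8 to 28 ± 7.32 CPM (0.000174) and the origin licensing factor CDC6 from 80.8 ± 2.84 to 23.2 ± 11.7 CPM (0.00124). Of the secreted proteins 1 of 23 measured members rose and 15 fell (1 and 15 adjusted over the list alone) (list 6.37e-06, adjusted p = 0.093 with an estimated correlation). The retinol carrier RBP4 fell from 2970 ± 130 to 199 ± 47.1 CPM and albumin, ALB, from 58.9 ± 3.1 to 8.35 ± 7.94 CPM. Oxidative phosphorylation had 16 of 23 lower and 0 higher (0 and 16 adjusted over the list alone, list 0.000253, adjusted p = 0.0577 with an estimated correlation). The unfolded protein response had 11 of 19 lower and 0 higher (0 and 11 adjusted over the list alone, list 0.0119, adjusted p = 0.138 with an estimated correlation). Of the ATF4 list 2 of 21 measured members rose and 13 fell (3 and 13 adjusted over the list alone) (list 0.0022, adjusted p = 0.365 with an estimated correlation). TRIB3 fell from 270 ± 10.8 to 43.8 ± 13.6 CPM, while DDIT3, a mediator of stress-induced cell death, rose from 12.3 ± 1.51 to 72.5 ± 62.8 CPM. Of the fatty acid oxidation genes 1 of 18 measured members rose and 10 fell (1 and 11 adjusted over the list alone) (list 0.00276, adjusted p = 0.339 with an estimated correlation). That call was lost once the trends with GC content and amplicon length were removed (0.0642, the median going from -0.76 to -0.37).

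The fibroblast and smooth muscle list passed upward in HuH7, where 8 of 18 measured members rose and 1 fell (8 and 1 adjusted over the list alone) (adjusted p = 0.0344, adjusted p = 0.135 with an estimated correlation). It missed without HuH7 in ovo replicate 4 (0.0537) and under the stricter filter (0.0522). Among its matrix genes, SPARC rose from 8.42 ± 0.754 to 401 ± 118 CPM, COL1A1 from 1.96 ± 0.0819 to 59.2 ± 28.5 CPM and COL6A1 from 59.6 ± 4.73 to 272 ± 45.6 CPM, while the proteoglycan LUM fell from 200 ± 4.16 to 26 ± 13.2 CPM. CYP2E1, an alcohol-oxidising enzyme of mature hepatocytes, rose from 3.3 ± 0.775 to 37.8 ± 13.9 CPM (6.09e-07) and the angiogenic factor VEGFA from 200 ± 6.06 to 786 ± 486 CPM (0.000731). HuH7 tumours had 3095 genes higher and 2593 lower, 1902 and 1554 by at least 2-fold. The balance turned with total counts alone as the scale (2528 higher and 3041 lower) and with the GC and length trends removed (2599 and 2789). With HuH7 fitted alone 1390 were lower. The olfactory receptor amplicons were read at 26.2% ± 4.33 in ovo and 6.8% ± 1.03 in vitro.

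PLC/PRF/5 gave the fewest calls, 2292. HepG2 gave fewer with each line fitted alone (2469 against 3508) and without HepG2 in ovo replicate 3 (2728 against 2787). The largest rise was that of a chemokine. CCL22 (chromosome 16, 57360446 to 57363513) rose from 1.93 ± 0.676 to 570 ± 260 CPM (log2 fold change 7.52, adjusted p = 3.65e-16). The 6 next in order, with APOA1 (7.17), AFP (6.36) and SERPINA1 (6.20) first, are genes abundant in HepG2 tumours. Of the hypoxia response, carbonic anhydrase 9, CA9, a direct target of hypoxia-inducible factor (chromosome 9, 35679907 to 35680754), rose from 21.9 ± 2.6 to 396 ± 109 CPM (4.07, 9.31e-12), and the glucose transporter SLC2A3 from 9.31 ± 0.992 to 243 ± 72.4 CPM (6.13e-09). NDRG1 rose from 160 ± 18.9 to 2196 ± 1190 CPM (1.99e-06) and hexokinase 2, HK2, from 223 ± 15.7 to 1461 ± 469 CPM (3.77e-06). HNF4A, a master regulator of hepatocyte identity, rose from 15.9 ± 2.29 to 136 ± 60.1 CPM (1.88e-07). The largest falls were those of FOSB, from 71 ± 2.16 to 1.86 ± 0.442 CPM (1.98e-13), and EPB41L3, from 89.9 ± 8.36 to 5.84 ± 2.46 CPM (3.89e-11). Placental alkaline phosphatase, ALPP (chromosome 2, 232380256 to 232380479), fell from 2038 ± 235 to 229 ± 76.3 CPM (5.62e-12).

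Of the hypoxia-inducible genes 18 of 25 measured members rose and 0 fell (18 and 0 adjusted over the list alone), the list passing at 1.37e-11 and also with an estimated correlation (0.0305). Of the glycolysis genes 10 of 20 measured members rose and 0 fell (10 and 0 adjusted over the list alone) (list 0.000282, adjusted p = 0.2 with an estimated correlation). Of the hepatocyte transcription factors 9 of 18 measured members rose and 0 fell (9 and 0 adjusted over the list alone) (list 2.19e-05, adjusted p = 0.0662 with an estimated correlation). CEBPA rose from 3 ± 0.535 to 63.1 ± 47.8 CPM. Of the NRF2 targets 1 of 20 measured members rose and 10 fell (2 and 11 adjusted over the list alone) (list 2.19e-05, 0.00255 with an estimated correlation). The cystine transporter SLC7A11 (chromosome 4, 138232368 to 138241864) fell from 48.4 ± 5.38 to 7.32 ± 4.7 CPM. Of the ATF4 list 0 of 21 measured members rose and 6 fell (0 and 6 adjusted over the list alone) (0.00162, adjusted p = 0.242 with an estimated correlation). Of the TGF-beta and YAP targets 2 of 16 measured members rose and 5 fell (3 and 5 adjusted over the list alone) (list 0.00637, adjusted p = 0.173 with an estimated correlation). CTGF fell from 50.6 ± 2.59 to 9.62 ± 2.54 CPM. Mitosis and oxidative phosphorylation passed downward at 0.00311 and 0.00311 with 2 members lower and 0 higher in each (0 and 2 adjusted over the list alone for mitosis, 0 and 1 adjusted over the list alone for the other). An estimated correlation gave an adjusted p = 0.0662 and an adjusted p = 0.117. Of the fatty acid oxidation genes 1 of 18 measured members rose and 3 fell (1 and 5 adjusted over the list alone) (0.0189, adjusted p = 0.327 with an estimated correlation, and 0.125 with the GC and length trends removed, the median being -0.29 before and -0.34 after).

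Reads of liver products were also more frequent in PLC/PRF/5 tumours. Of the secreted proteins 16 of 23 measured members rose and 0 fell (19 and 0 adjusted over the list alone) (list adjusted p = 1.29e-22). Of the acute phase response 11 of 17 measured members rose and 0 fell (12 and 0 adjusted over the list alone) (1.11e-08). Of the oncofetal markers 10 of 18 measured members rose and 3 fell (10 and 4 adjusted over the list alone) (0.000282). Of the Wnt/beta-catenin targets 7 of 18 measured members rose and 1 fell (9 and 1 adjusted over the list alone) (0.000666). Of the urea cycle genes 4 of 17 measured members rose and 0 fell (5 and 0 adjusted over the list alone) (0.0292). With an estimated correlation the first 2 passed and the other 3 had an adjusted p = 0.0662, an adjusted p = 0.0662 and an adjusted p = 0.156. APOA1 was read at 0.462 ± 0.259 CPM in vitro and 232 ± 135 CPM in ovo, and AFP at 0.849 ± 0.452 and 154 ± 58.6 CPM. Alpha-1-antitrypsin, SERPINA1, was read at 3.84 ± 1.49 and 363 ± 147 CPM, and transferrin, TF, at 2.84 ± 0.913 and 274 ± 129 CPM. Over 72 genes abundant in HepG2 tumours and silent in PLC/PRF/5 cultures, the PLC/PRF/5 in ovo libraries had a median share of the HepG2 in ovo level. It was 1.01%, 0.959%, 1.06% and 1.78% in replicates 1 to 4. A constant share is only approximate, as 123 less abundant genes not used for it had a median of 1.23 observed over predicted reads. That share predicts 132% of the level of APOA1, 141% of AFP, 161% of SERPINA1 and 145% of TF, and under 1% of CCL22, CA9, NDRG1 and HK2. Subtracting the share thus takes more than the level read for the first 4 of these genes, so the negative log2 fold changes left, -0.86 for AFP, -0.54 for APOA1, -2.24 for SERPINA1 and -1.92 for TF, follow from that excess and measure no fall. With the share subtracted HNF4A kept 2.62 and CA9 4.07. The 5 lists then no longer passed, at 0.212 for secreted proteins, 0.179 for the acute phase response, 0.179 for oncofetal markers, 0.0649 for Wnt targets and 0.613 for the urea cycle. Ceruloplasmin, CP (from 8.11 ± 0.747 to 57.5 ± 22.3 CPM), lipocalin, LCN2 (from 39.4 ± 2.41 to 235 ± 143 CPM), and the Wnt target AXIN2 (from 3.33 ± 1.27 to 15.8 ± 6.32 CPM) remained higher.

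Of the unfolded protein response 4 of 19 measured members rose and 0 fell (4 and 0 adjusted over the list alone), and of the inflammatory mediators 5 of 21 measured members rose and 0 fell (9 and 0 adjusted over the list alone). These lists passed upward at 0.0425 and 0.0337 (an adjusted p = 0.207 for each with an estimated correlation). The first was lost under 8 other settings, up to 0.14 under the stricter filter. The other was lost without PLC/PRF/5 in ovo replicate 1 (0.108) or replicate 4 (0.0501) and with a pseudocount of 0.25 CPM (0.0545). Of the fibroblast list 3 of 18 measured members rose and 5 fell (3 and 6 adjusted over the list alone). It passed downward at 0.019 (adjusted p = 0.101 with an estimated correlation, 0.731 under the stricter filter) with a median near 0. PLC/PRF/5 had 1557 genes higher and 735 lower, 819 and 345 by at least 2-fold, and 1279 of the 1557 stayed higher with the HepG2 share subtracted. Size factors by the median of ratios gave 1174 and 1049, and total counts alone 1277 and 1202. Without PLC/PRF/5 in vitro replicate 2 the counts were 927 and 438, and without the in ovo libraries numbered 3 they were 2353 and 1451. Between 1114 and 1317 genes were lower with DESeq2, with the line fitted alone or with the GC and length trends removed. The olfactory receptor amplicons were read at 23.8% ± 15.1 in ovo and 2.72% ± 0.779 in vitro.

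**Figure D2:**
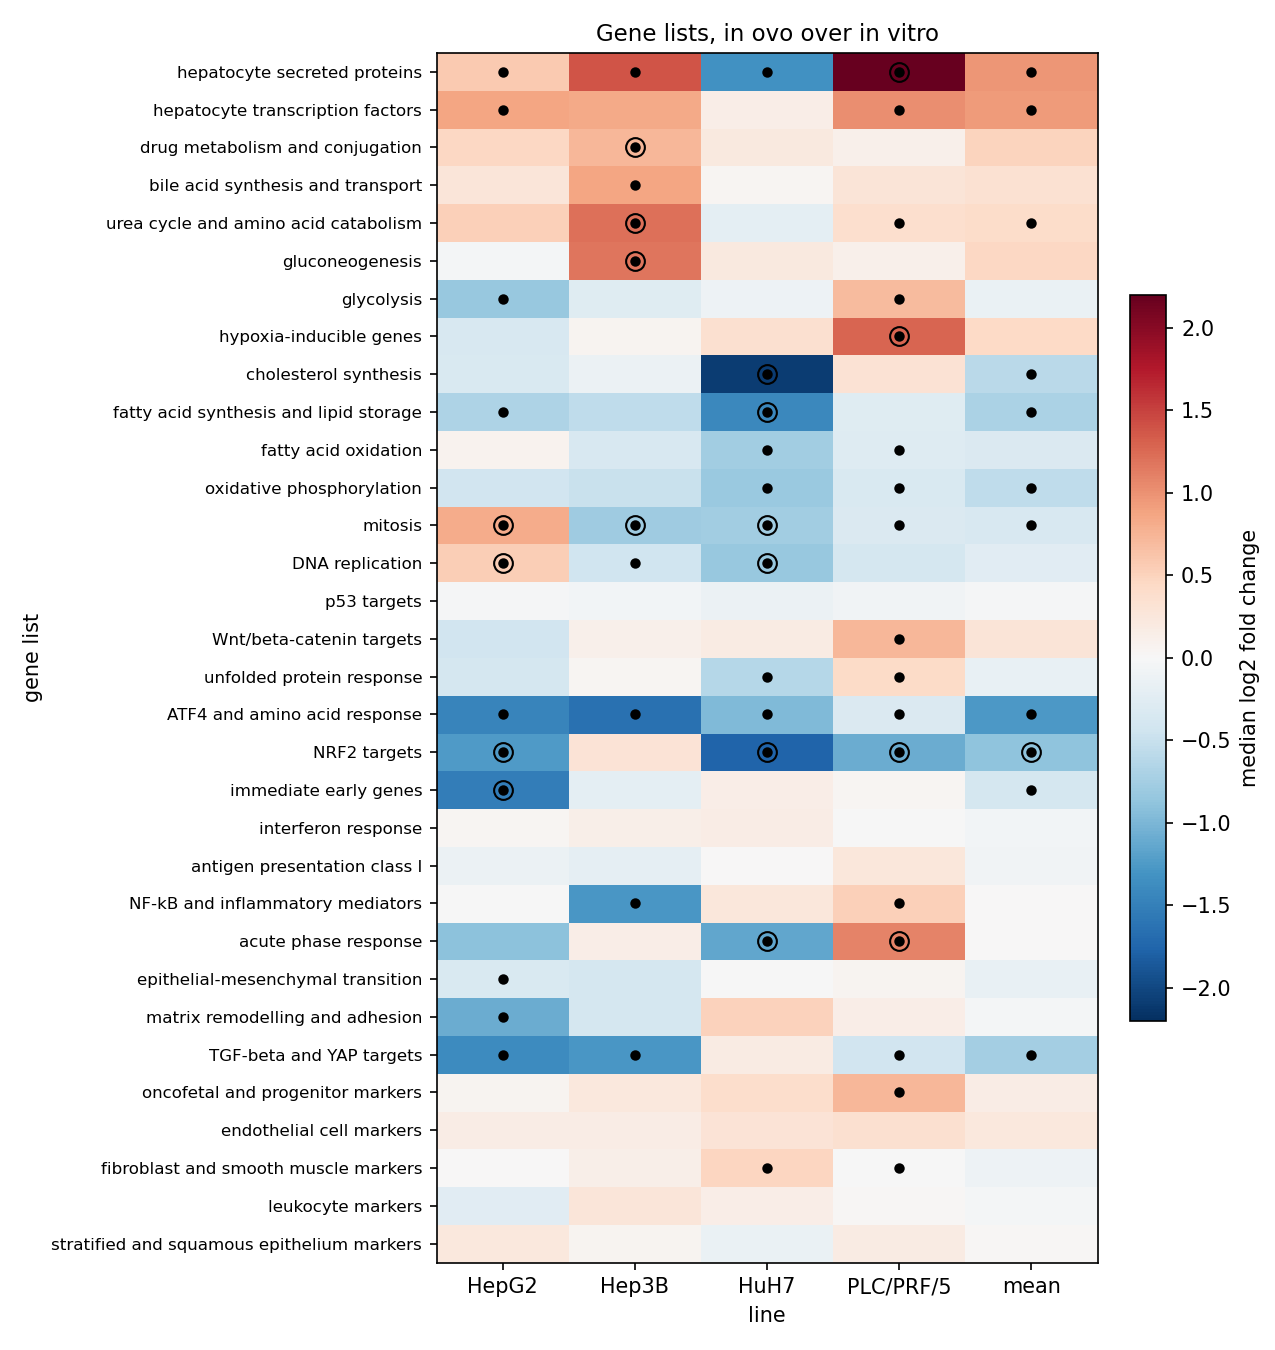
Median log2 fold change, in ovo over in vitro, of each of the 32 tested gene lists (vertical) in the 4 lines and their mean (horizontal), with a dot where the list passed camera at an adjusted p under 0.05 and a ring where it also passed with an estimated correlation. The NRF2 list is negative and marked in HepG2, HuH7, PLC/PRF/5 and the mean, and the mitosis list is positive in HepG2 and negative in the other 3 lines.

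A small set of genes moved the same way in all 4 lines. Higher in each were 200 genes and lower 80, where independent lists of these sizes would share 11 and 5.17. The lines are not independent, as they share the difference of RNA kit and trends with GC content and amplicon length of the same sign. With these trends removed the counts were 140 and 125. How much of the excess such shared differences make was not tested. FOSB fell by 4.20 on the log2 scale over the mean of the lines (adjusted p = 1.77e-18) and FOS by 3.12 (5.37e-15), both components of the AP-1 transcription factor. SLC7A11 fell from 44 ± 1.12 to 3.62 ± 2.25 CPM in HepG2 and from 8.4 ± 1.02 to 0.827 ± 0.953 CPM in Hep3B. It fell from 19.6 ± 1.4 to 2.09 ± 0.795 CPM in HuH7 and from 48.4 ± 5.38 to 7.32 ± 4.7 CPM in PLC/PRF/5, with no detected difference between lines (interaction adjusted p = 0.466). The serine synthesis enzyme PSAT1 fell by 1.93 (5e-07, interaction 0.865), its HepG2 call being lost with that line fitted alone (0.0658) and its PLC/PRF/5 call without in vitro replicate 2 (0.0578) or in ovo replicate 3 (0.0531). CTGF (chromosome 6, 131950032 to 131950145) fell by 2.23 (3.32e-11), though the HuH7 call of CTGF (0.031) was lost under 10 other settings, up to 0.133 with that line fitted alone and 0.3 with donor shares subtracted. That subtraction took nothing from the HuH7 libraries, and the log2 fold change of CTGF there was -0.84 before it and -0.82 after. The actin nucleator COBL (chromosome 7, 51028369 to 51028485) rose from 10.7 ± 0.778 to 52 ± 28.2 CPM in HepG2 and from 23.3 ± 1.46 to 147 ± 51.3 CPM in Hep3B. It rose from 23.9 ± 1.38 to 166 ± 88.7 CPM in HuH7 and from 17.3 ± 1.29 to 87.8 ± 28.3 CPM in PLC/PRF/5 (interaction 0.708). AGT and IGF2, also called higher in all 4 lines, kept no rise in PLC/PRF/5 with the HepG2 share subtracted (-0.82 and -2.93 on the log2 scale). The IGF2 call in HuH7 (0.0206) was lost under 7 other settings, among them total counts alone (0.0609), the line fitted alone (0.185) and the GC and length trends removed (0.105). In HepG2 it was lost with the line fitted alone (0.0789). With shares subtracted from both PLC/PRF/5 (HepG2) and Hep3B (HuH7), 160 of the 200 genes were kept.

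Over the mean of the 4 lines 4410 genes were higher and 4271 lower, 981 and 978 by at least 2-fold, and 11 lists passed camera, 3 upward and 8 downward. In 30 of 100 splits of the libraries, the real one included, as many lists passed. Of the NRF2 targets 2 of 20 measured members rose and 14 fell (2 and 14 adjusted over the list alone) (8.91e-05). This list alone also passed with an estimated correlation (0.0121). AKR1C2 changed by -2.58 and NQO1 by -2.24 on the log2 scale. Of the ATF4 list 1 of 21 measured members rose and 16 fell (1 and 17 adjusted over the list alone) (1.46e-05). In fatty acid synthesis 2 of 19 measured members rose and 12 fell (2 and 12 adjusted over the list alone) (0.00139). In oxidative phosphorylation 2 of 23 measured members rose and 16 fell (2 and 16 adjusted over the list alone) (0.00591). Among the TGF-beta and YAP targets 2 of 16 measured members rose and 11 fell (2 and 11 adjusted over the list alone) (0.00139). An estimated correlation gave each of these 4 an adjusted p = 0.192. In cholesterol synthesis 2 of 23 measured members rose and 15 fell (3 and 16 adjusted over the list alone) (0.00795, adjusted p = 0.366 with an estimated correlation). Among the immediate early genes 1 of 20 measured members rose and 10 fell (1 and 10 adjusted over the list alone) (0.00795, adjusted p = 0.27 with an estimated correlation). In mitosis 4 of 25 measured members rose and 13 fell (4 and 13 adjusted over the list alone) (0.0385, adjusted p = 0.224 with an estimated correlation). Mitosis missed without HuH7 in ovo replicate 4 (0.0508), with the GC and length trends removed (0.0566) and with the donor shares subtracted (0.0528). Its median log2 fold change was then -0.348, -0.272 and -0.36. Upward, 18 of 23 measured members rose and 4 fell (18 and 4 adjusted over the list alone) among the secreted proteins (4.18e-05, adjusted p = 0.192 with an estimated correlation). Among the hepatocyte transcription factors 13 of 18 measured members rose and 3 fell (13 and 3 adjusted over the list alone) (0.00795, adjusted p = 0.27 with an estimated correlation). In the urea cycle 11 of 17 measured members rose and 2 fell (12 and 2 adjusted over the list alone) (0.00894, adjusted p = 0.192 with an estimated correlation). With shares subtracted from both PLC/PRF/5 (HepG2) and Hep3B (HuH7), secreted proteins had 0.149 and the urea cycle 0.0505. Total counts alone as the scale moved the median of all genes by -0.29 and gave 2646 genes higher and 6427 lower, with 100 and 158 in all 4 lines. The stricter filter left 2807 lower. The counts in all 4 lines fell to 117 and 46 without PLC/PRF/5 in vitro replicate 2, were 128 and 51 without HepG2 in vitro replicate 1, and were 340 and 209 without the in ovo libraries numbered 3.

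The lines also differed in their response. A line by condition interaction was detected for 5478 genes, 41.8% of those tested, and 1162 genes were higher in at least 1 line and lower in another. AFP rose in HepG2 and Hep3B and fell in HuH7 (interaction adjusted p = 1.73e-15). SERPINC1 rose from 112 ± 3.81 to 377 ± 118 CPM in HepG2 and fell from 4.1 ± 0.45 to 1.05 ± 0.369 CPM in HuH7 (interaction 1.65e-15). CER1 fell in Hep3B and rose in HuH7 (interaction 2.08e-14). ABCC3 fell in HepG2 and PLC/PRF/5 and rose from 53.4 ± 3.4 to 134 ± 22.4 CPM in HuH7 (interaction 3.07e-15). ENPP2, which makes lysophosphatidic acid, rose from 2.65 ± 1.17 to 52.4 ± 9.85 CPM in HepG2 and fell from 436 ± 12.6 to 84.3 ± 9.27 CPM in Hep3B and from 294 ± 14.3 to 77.1 ± 18.9 CPM in HuH7 (interaction 3.49e-14). The synaptic protein SNAP25 fell from 97 ± 2.26 to 33.9 ± 9.03 CPM in Hep3B and rose from 5.45 ± 0.324 to 121 ± 35.7 CPM in HuH7 (interaction 7.14e-13). Calls nevertheless coincided between pairs of lines. Hep3B and HuH7 shared 1661 higher and 1608 lower genes, against 760.8 and 711.4 for independent lists. 417 genes were called in opposite directions in these lines, against 1486. Across genes their fold changes correlated at 0.512, the highest of the 6 pairs, and the lowest was 0.323 for HepG2 and PLC/PRF/5. Hep3B and HuH7 are also the lines whose fold changes followed GC content most closely (Spearman's rho 0.458 and 0.505). Over 20 genes expressed in HuH7 and silent in Hep3B cultures, Hep3B tumours had a median of 0.314% to 2.78% of the HuH7 in ovo level. No genes were held out to test a constant share, and replicate 4 spread too widely for one (log2 interquartile range 3.03). How far the GC trend or such reads raise the agreement of this pair was not tested.

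**Figure D3:**
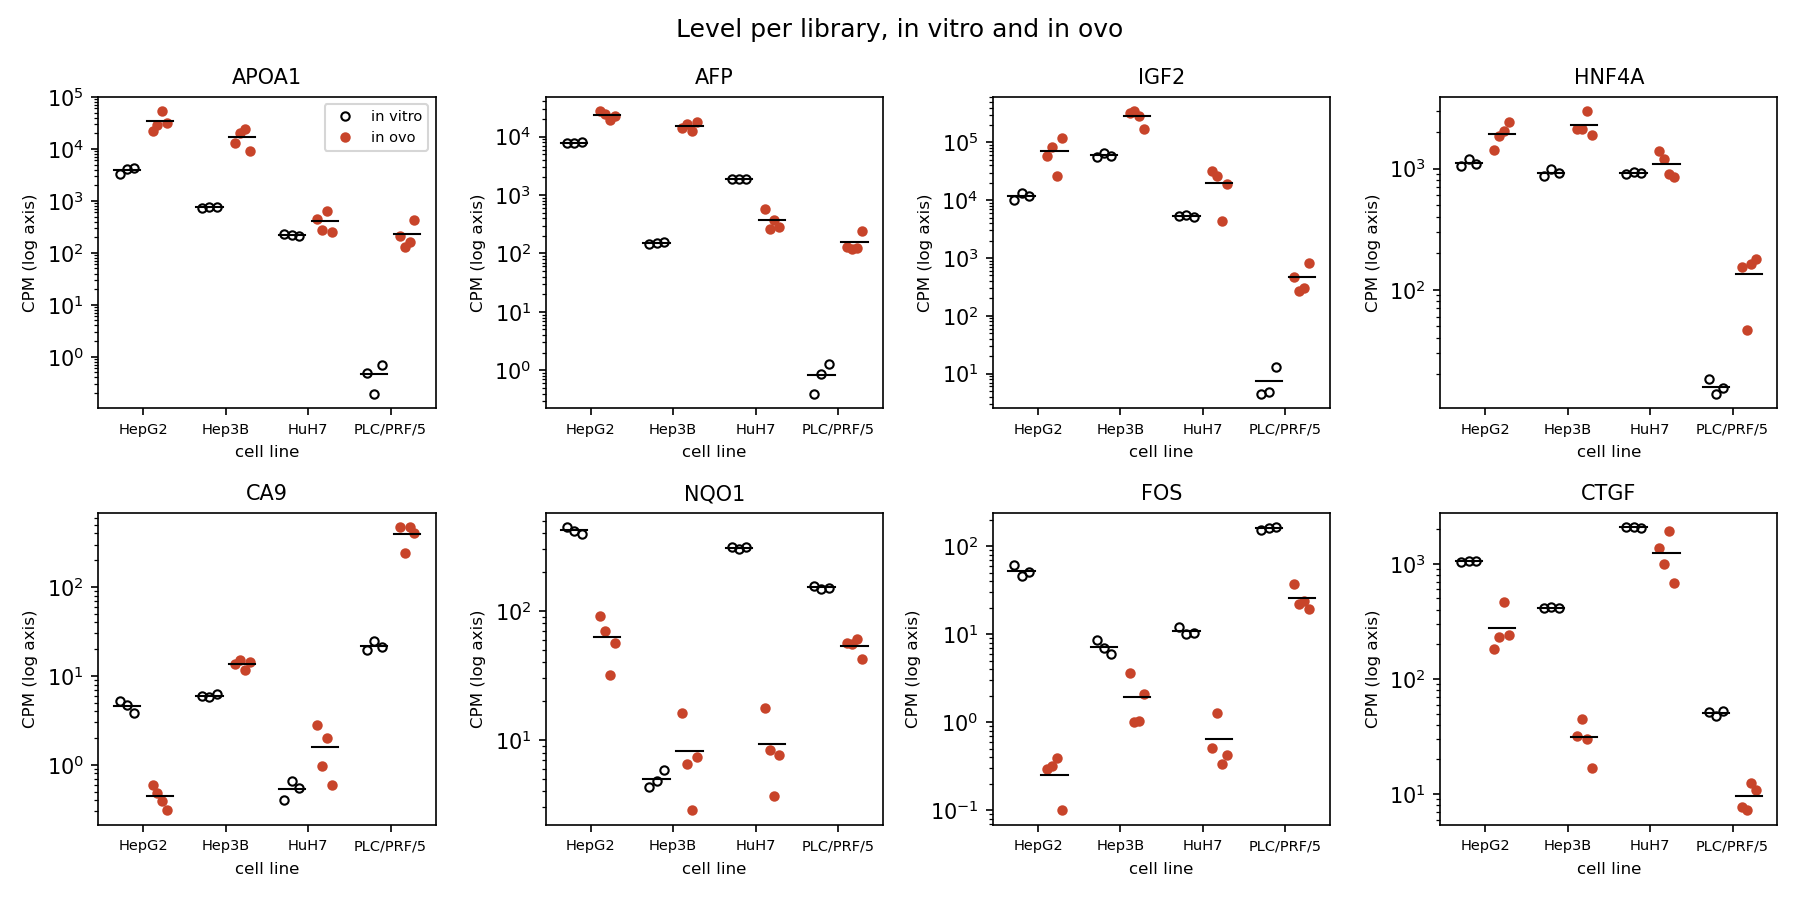
Level in each library of 8 genes (CPM on a log axis, values under 0.1 drawn at 0.1), with in vitro libraries as open and in ovo libraries as filled circles and the group mean as a line. FOS and CTGF are lower in ovo in the means of all 4 lines, NQO1 in those of all lines but Hep3B, and AFP is higher in HepG2 and Hep3B and lower in HuH7.

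Markers of other cell types gave no common pattern. The tumours grew on a chick membrane and the amplicons are human, so these lists cannot measure the presence of host cells. Whether chick RNA was read by any amplicon was not tested. The endothelial list had 7 measured members and passed in no line (adjusted p 0.837, 0.374, 0.669 and 0.197 in HepG2, Hep3B, HuH7 and PLC/PRF/5), although PECAM1 rose from 8.35 ± 1.17 to 47.3 ± 3.53 CPM in HepG2 (4.47e-07) and EGFL7 from 122 ± 20 to 449 ± 223 CPM in HuH7 (0.00235). Of the endothelial members 2, 3, 3 and 3 were higher and 2, 0, 1 and 0 lower. PECAM1 was called lower in HuH7, a call lost with that line fitted alone (log2 fold change -1.18, adjusted p = 0.0753). EGFL7 was also called higher in Hep3B and PLC/PRF/5, calls lost under some other settings. The leukocyte list, 9 measured members, came nearest in HepG2 (0.0503), where 0 of 9 measured members rose and 4 fell (0 and 4 adjusted over the list alone) and the lysozyme gene LYZ fell from 381 ± 6.62 to 37.3 ± 23 CPM, and had 0.427, 0.685 and 0.495 in the other 3. The stratified epithelium list had 7 measured members and 0.809, 0.958, 0.731 and 0.417 in the 4 lines, with KRT17 rising from 348 ± 44.6 to 1605 ± 606 CPM in PLC/PRF/5. The list of erythroid genes had too few measured members to test. The fibroblast list had 0.547 in HepG2 and 0.733 in Hep3B.

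Other fixed lists passed in no line nor in the mean of lines. For p53 targets the adjusted p was 0.279, 0.533, 0.677 and 0.269 in HepG2, Hep3B, HuH7 and PLC/PRF/5. It was, in the same order, for the interferon response 0.809, 0.41, 0.677 and 0.0683, and for class I antigen presentation 0.601, 0.596, 0.669 and 0.912. Of the p53 targets 8 of 25 measured members rose and 3 fell (8 and 6 adjusted over the list alone) in HepG2 and 5 of 25 measured members rose and 10 fell (5 and 10 adjusted over the list alone) in Hep3B. Of the interferon genes 8 of 20 measured members rose and 6 fell (8 and 6 adjusted over the list alone) in the mean of lines, where the median was -0.06 and the mean 0.08, and of the antigen presentation genes 4 of 14 measured members rose and 3 fell (4 and 3 adjusted over the list alone). Single genes of the Wnt list moved far: the antagonist DKK1 rose from 1622 ± 123 to 12770 ± 7080 CPM in HepG2 (4.36e-05) and fell from 30190 ± 2020 to 3163 ± 2710 CPM in Hep3B (8.35e-07), and glutamine synthetase, GLUL, rose from 561 ± 24.6 to 7293 ± 2880 CPM in Hep3B (4.71e-10). Among the key genes, KRT19 and EPCAM, markers of biliary and progenitor cells, did not pass in HepG2, HuH7 or PLC/PRF/5, and EPCAM fell from 414 ± 7.31 to 181 ± 60.8 CPM in Hep3B (0.0108). KRT19 fell there from 1057 ± 63.1 to 548 ± 390 CPM (0.0231, and 0.0979 with the line fitted alone). The mesenchymal filament gene VIM had no read in HepG2 and fell from 2.35 ± 0.24 to 0.653 ± 0.512 CPM in Hep3B (0.00123, and 0.699 with the GC and length trends removed). In HuH7 VIM rose from 3.31 ± 0.656 to 5.82 ± 2.03 CPM (0.0494), a call lost under 15 other settings, up to 0.214 with total counts alone. CYP3A4 lay below the expression filter, and HBB is not analysed here.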

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

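The tests of exchange both ways, of a change of the PLC/PRF/5 cells themselves, of read number, of wider transcription, of depth rank and of the order of handling, and the subtraction of donor profiles, were chosen after the results they address were seen. For exchange both ways, the ratio of 5th percentiles alone (0.57) had come out in favour of exchange before the ratio of shares was added. For genomic DNA, the demand that an interval also lie under the bound was added after the value was seen. Read number was first tested by a rank correlation of detection with depth over the 16 in ovo libraries, which was near 0, and the gap at equal reads then took its place.

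In 83 groups of 4 in ovo libraries, for key genes and measures of the libraries, Dixon's test set 7 single libraries apart, where chance gives about 1 in 20 (4.15 of 83). HepG2 in ovo replicate 3 had 248 CPM of TTR (other libraries of the group 89.5 to 107), 46.3 CPM of EPCAM (157 to 194) and 13.8 CPM of MKI67 (88.6 to 111). Hep3B in ovo replicate 4 had 6.7 CPM of CDKN1A (20.6 to 24.5), and Hep3B in ovo replicate 1 had 13787 genes with a read (12966 to 12986). PLC/PRF/5 in ovo replicate 2 had 46.5 CPM of HNF4A (155 to 178), and PLC/PRF/5 in ovo replicate 4 had 242 CPM of AFP (121 to 129).

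Of the 19 key genes reported here, 17 differed between lines in their response (limma interaction test). The distance between the highest and the lowest line, in log2 units, was 9.04 for AFP (adjusted p = 1.73e-15), 6.39 for APOA1 (5.12e-09), 5.16 for TTR (2.86e-06), 3.34 for ALB (0.0111), 5.4 for CPS1 (1.47e-12), 2.65 for HNF4A (0.000146) and 2.77 for CYP2E1 (0.00128), all products or regulators of hepatocytes. It was 6.01 for CA9 (2.11e-11) and 2.18 for VEGFA (0.0105) of the hypoxia response, and 1.98 for TOP2A (4.5e-09) and 2.39 for CDKN1A (0.00161) of the cell cycle. GPC3, an oncofetal surface protein, spread over 5.47 (4.56e-10), EPCAM over 1.95 (0.0379), CTGF over 2.95 (6.58e-05), VIM over 1.7 (0.00221), SPP1 over 4.16 (3e-06) and COL1A2 over 2.07 (0.00284). PLC/PRF/5 is the highest line for APOA1 and GPC3, and with donor profiles subtracted the distance was 4.92 (3.95e-09) for APOA1 and 1.89 (0.0433) for GPC3. That of CTGF became 6.07 (2.6e-05), and that of SPP1 3.15 (3.01e-06). For CTGF the highest line, HuH7, stayed at -0.82, so the wider distance comes from lines whose reads were subtracted and measures no deeper fall.

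For each list only the line with the smallest p is given, and other lines differed as well in many of them. Among lists, the median difference of 1 line from the mean of the others was largest in HuH7 for hepatocyte secreted proteins (-3.15 in log2 units, camera adjusted p = 1.82e-27) and cholesterol synthesis (-2.14, 4.06e-17). HuH7 also differed in fatty acid synthesis (-1.04, 2.92e-05), fatty acid oxidation (-0.57, 0.00118), the unfolded protein response (-0.56, 0.000586), oxidative phosphorylation (-0.46, 0.0207), hepatocyte transcription factors (-0.35, 0.0351), TGF-beta and YAP targets (1.19, 1.26e-06) and fibroblast markers (0.77, 0.000205). HepG2 stood apart in mitosis (1.41, 1.56e-16), DNA replication (1.28, 1.04e-13), p53 targets (0.35, 0.0283), immediate early genes (-1.81, 3.1e-07) and matrix remodelling (-0.83, 2.97e-05). Hep3B stood apart in the urea cycle (1.38, 4.63e-07), NRF2 targets (1.36, 2.04e-07), gluconeogenesis (0.997, 0.00356), bile acids (0.96, 0.00249), drug metabolism (0.58, 0.00381) and inflammatory mediators (-0.89, 1.56e-05). PLC/PRF/5 stood apart in the acute phase response (1.8, 6.71e-11), glycolysis (1.52, 3.1e-07), hypoxia (1.49, 1.77e-09), oncofetal markers (1.07, 0.00495), Wnt targets (0.48, 0.0303) and the interferon response (-0.22, 0.0228). With donor profiles subtracted the oncofetal difference turned (-0.42, 0.006), where the share exceeds the level of several members, that of Wnt targets was lost (0.34, 0.476) and that of the acute phase response was 0.85 (0.00204). Hepatocyte secreted proteins in HuH7 then had -2.69 (7.35e-19), and hepatocyte transcription factors in HuH7 were lost (-0.30, 0.121). In PLC/PRF/5 itself, the acute phase (0.179), oncofetal (0.179) and Wnt (0.0649) lists then no longer passed between in ovo and in vitro.

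Genes that HepG2 expresses and PLC/PRF/5 cultures do not were read in all 4 PLC/PRF/5 in ovo libraries. RNA or reads of the HepG2 in ovo libraries are a candidate source. Over 123 such genes not used to estimate the share, observed over predicted reads had a median of 1.23 (interquartile range 1.03 to 1.55), with 104 within 2-fold. More abundant genes went the other way, the share predicting 132% of the level of APOA1, 145% of TF, 146% of IGF2 and 161% of SERPINA1. A constant share is thus only approximate. A change of the PLC/PRF/5 cells themselves was taken to scatter such genes widely. Over the 72 genes used to estimate the share, the ratio to the HepG2 in ovo level had a log2 interquartile range of at most 0.843 in any library. Liver genes raised together could also keep a narrow range, so this test cannot exclude such a change. HNF4A and CEBPA rose in PLC/PRF/5 tumours, and the share predicts 13.3% and 1.48% of their levels there. The median over libraries of the log2 interquartile range was 0.6 against the HepG2 in ovo profile and 1.44 against the HepG2 cultures. It was 2.66 against the Hep3B tumours and 7.32 against the HuH7 tumours. The genes were chosen for a high level in HepG2 tumours, so a wider range against other profiles is partly built in. Exchange in both directions is excluded by the share of PLC/PRF/5 in HepG2 tumours (ratio 0.0131), while the 5th percentiles alone gave 0.57, and whether HepG2 material entered, and at which step, stays open.

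Among amplicons of genes below the expression filter, those within 1 exon were read more often in ovo in the mean of every line, and so were olfactory receptors. Of the 392 olfactory receptor amplicons 27.8% were read in HepG2 tumours (cultures 3.06 to 4.08%) and 19.8% in Hep3B (3.57 to 3.83%). In HuH7 it was 26.2% (5.87 to 7.91%) and in PLC/PRF/5 23.8% (2.04 to 3.57%). Single libraries varied. HepG2 in ovo replicate 1 read 15.9% of the single-exon amplicons, within the 14.5 to 16.2% of its cultures, and 5.61% of the olfactory receptors. Replicate 2 read 66.1% and 51.8%. Wider transcription in ovo would raise amplicons across exon junctions too, but these went from 23% to 21.8% while single-exon amplicons went from 15.9% to 35.2% (ratio of rises -0.0656), and by line junction amplicons went from 21.3% to 19.8% in HepG2, 21.9% to 15.3% in Hep3B, 25.7% to 27.3% in HuH7 and 23.3% to 24.7% in PLC/PRF/5. A higher number of reads is excluded as the whole cause, because with every library taken at equal reads the gap of 19.3 percentage points was still 16.4 (ratio 0.851). Genomic DNA in the tumour RNA cannot be told apart from other sources: amplicons with several matches had 0.965 times the in ovo reads of those with 1 match, under the bound of 1.1 set beforehand, but the interval of 0.708 to 1.24 over 87 and 3277 amplicons reaches past that bound. In the cultures that ratio was 0.413. The rise from cultures to tumours was 1.43 times as large for amplicons with several matches, a value without an interval that runs toward genomic DNA.

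The 4 in ovo libraries numbered 3, 1 per line, deviated together from their groups (mean correlation across genes over 6 pairs 0.522; genes are not independent replicates). Removing the trends with GC content and amplicon length left 0.441 (SE over pairs 0.108), so these trends are not the whole cause. Depth is excluded as a common cause, since at most 2 of the 4 shared a depth rank in their group. Each of the 4 had the fewest genes with at least 10 reads in its group (8779, 8050, 9322 and 10492 in HepG2, Hep3B, HuH7 and PLC/PRF/5). Each also had the lowest MKI67 of its group (13.8, 40.4, 9.1 and 53.5 CPM in the same order). An order of handling shared by the number cannot be told apart, since these 4 share the letter D in their titles, of a meaning not given in the sources used here, while number 4, lettered E in every line, gave 0.21 and numbers 1 and 2, which mix letters, gave 0.0293 and 0.137. No biological explanation was tested.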

How the results depend on the processing

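The tests with edgeR on recovered reads, other pseudocounts, the GC and length trends removed, the libraries numbered 3 left out and donor profiles subtracted were chosen after the data were seen. A minimum of 2-fold left 844 genes higher and 1098 lower in HepG2, 2016 and 2380 in Hep3B, 1902 and 1554 in HuH7, 819 and 345 in PLC/PRF/5, 981 and 978 in the mean of lines, and 46 and 28 in all 4 lines. It removes small changes by its construction. Total counts alone as the scale gave 1205 higher and 6820 lower in Hep3B, 1202 lower in PLC/PRF/5, 2646 and 6427 in the mean, and 100 and 158 in all 4 lines. TMM is what separates this setting, since without it the median of all genes shifts by -0.69 in Hep3B and by -0.29 in the mean. The stricter filter gave 2332 lower in Hep3B and 2807 lower in the mean of lines, having fewer genes to call. It raised the correlation of the line differences of PLC/PRF/5 from 0.889 to 0.9, where the SD over in ovo libraries is 0.00855. Each line fitted alone gave 1390 lower in HuH7, 1317 lower in PLC/PRF/5 and 52 lower in all 4 lines. DESeq2's test gave 1114 lower in PLC/PRF/5 and 132 lower in all 4, the GC and length trends removed 1229 and 125, and the libraries numbered 3 left out 2353 higher and 1451 lower in PLC/PRF/5 and 340 and 209 in all 4. Lower in all 4 lines were 47 genes with edgeR on recovered reads and 134 with a pseudocount of 5 CPM. In the mean of lines 1 list passed with an estimated correlation and 24 with fry, against 11. Where no construction is named, the cause was not tested.

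The replicate block gave 132 genes higher in all 4 lines. The replicate numbers were not taken to pair cultures with tumours, as deviations of libraries with the same number from their groups correlated at -0.0955 to 0.457 over 12 pairs, 5 of them over 0.1, and 4 of 12 were best with their own number. Under the block the lists of immediate early genes (0.0516) and mitosis (0.0588) missed in the mean of lines, and in PLC/PRF/5 those of the urea cycle (0.0618) and fibroblast markers (0.0886). The in ovo libraries numbered 3 deviate together across lines (mean correlation 0.522), so the lines are not independent in the mean and in the counts of genes in all 4 lines. Leaving out 1 library moved PLC/PRF/5 from 927 higher and 438 lower (without in vitro replicate 2) to 1655 and 803 (without in ovo replicate 2). It moved the genes in all 4 lines from 117 higher and 46 lower (without PLC/PRF/5 in vitro replicate 2) to 253 and 124 (without HepG2 in ovo replicate 1). The cause was not tested.

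With donor profiles subtracted, directions turned in PLC/PRF/5 for AFP (-0.86), AGT (-0.82), APOA1 (-0.54), APOB (-1.07), IGF2 (-2.93), SERPINA1 (-2.24), SERPINC1 (-0.0509) and TF (-1.92), as also for A2M (-0.433) and DLK1 (-0.664), and for GPC3 in the mean of lines (-0.20). Camera's direction there turned for the secreted proteins (median 0.144, adjusted p = 0.212) and the oncofetal markers (0.0423, 0.179), though both medians stayed positive and neither list passed. For AFP, AGT, APOA1, APOB, IGF2, SERPINA1, TF, A2M and DLK1 the share subtracted exceeds the level read (113% to 161% of it), so their turn is set by the subtraction and measures no fall. Of 24 PLC/PRF/5 genes followed through the subtraction 9 turned. GPC3 turned in Hep3B with total counts alone (-0.13), and ALB in the mean with edgeR (0.0781). LYZ turned in the mean with DESeq2 (0.43) and with edgeR (0.51), and TOP2A in the mean with the GC and length trends removed (0.082). Of 301 results of named genes, total counts alone left 277 as they were, with 15 calls lost and 8 gained. Each line fitted alone left 217 of 240, with 19 lost and 4 gained, and 1 library left out 3309 of 3388, with 74 lost and 5 gained. The GC and length trends removed left 281, with 13 lost and 6 gained, and the donor subtraction left 278, with 10 lost and 2 gained. Of 62 list results past the test 42 were kept under every alternative in which camera was run at the preset correlation. The lists were not tested with DESeq2's test, with each line fitted alone or with edgeR on recovered reads. With an estimated correlation 4 lists passed in HepG2, 4 in Hep3B, 6 in HuH7, 4 in PLC/PRF/5 and 1 in the mean. Depth sets the floor of 3 reads, 0.199 to 0.493 CPM before TMM scaling, under which levels are not resolved. On the scaled levels the floor is higher in Hep3B tumours, whose TMM factors were 0.447 to 0.711. At these depths and numbers of libraries, 2-fold changes were recovered in 36% to 45% of simulated cases, all of them genes averaging at least 10 CPM.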

Other observations

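All splits were planned before their results were seen, and the search for shares of other lines in the Hep3B libraries was chosen afterwards. Of the 35 ways to split a line's 7 libraries into 3 and 4, the real one called most genes in HepG2 (3285, highest other 2911), in Hep3B (6814, 6522) and in PLC/PRF/5 (2292, 1615), as 1 of 35 each. That is the lowest share this count can give, without correction for the number of lines tried, so it does not exclude chance. In HuH7 2 of 35 splits called as many (5688 in the real split, 6419 in another), so chance cannot be excluded there either. In each line the highest other split set 3 in ovo libraries against the cultures joined by 1 in ovo library, which was replicate 1 in HepG2 and Hep3B, replicate 4 in HuH7 and replicate 2 in PLC/PRF/5. Such a split keeps 3 of the 4 tumours apart from every culture, and what its calls rest on was not tested.

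Over 100 splits of all libraries, the real split alone gave as many called genes in the mean of lines (8681, highest other 2043). The same held for genes called higher in all 4 lines (200, highest other 0) or lower (80, highest other 0). It also held for genes with a line by condition interaction (5478, highest other 95), 1 of 100 each. That is again the lowest share this count can give. A split that mixes cultures with tumours adds their difference to the spread within groups, so low counts were likely beforehand. The lines are also not independent, as in ovo libraries with the same number can deviate together. These splits therefore do not exclude chance, and show only that none of the others gave as many. For the 11 lists past the test in the mean of lines, 30 of 100 splits gave as many and the highest gave 17, so a random grouping is not excluded there either.

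Over 20 genes expressed in HuH7 and silent in Hep3B cultures, the Hep3B in ovo libraries had a median of 1.09%, 2.78%, 1.28% and 0.314% of the HuH7 in ovo level in replicates 1 to 4, with log2 interquartile ranges of 0.799, 0.825, 1.04 and 3.03. No genes were held out to test these shares, and the range in replicate 4 is too wide for a constant share. The names of the deposited columns begin with what read as plate positions. By these, HepG2 and HuH7 tumours share 1 plate column, and PLC/PRF/5 and Hep3B tumours share the next. PLC/PRF/5 tumours stand in the rows of the HepG2 tumours (A to D) and Hep3B tumours in those of the HuH7 tumours (E to H). The plate column on the other side holds cultures of HepG2, HuH7 and PLC/PRF/5.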
